A study of Homo sapiens with 6 samples.

How the data were processed

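RNA of DMS114 cells was sequenced in 6 libraries, 3 control and 3 after 12 h in 200 mM trehalose, grouped by their titles. Per the labels, total RNA was taken with Trizol, selected with oligo(dT), made into strand-specific libraries by the dUTP method and sequenced as paired ends. The authors named hg38, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR in their processing notes without giving the role of each. The counting step, its strand setting and the annotation release are not given in the sources used here. The deposited table holds a count per gene and library, whole numbers with no scaling. It also holds the authors' FPKM, scaled by a length fixed per gene and by the total counts of the library. Length per gene, worked back from the deposited FPKM and counts, varied by a median of 0.183% between libraries over 11183 genes. The table has 37455 genes, each with an Ensembl ID, of which 37419 were in the reference name table and 10377 had no symbol. Its coordinates were checked against GENCODE, where 73.7% of 35489 genes had the same start and 65.6% the same end.

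Counts per library ranged from 54.4 to 61.5 M, and TMM factors from 0.989 to 1.01. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. The 95% intervals of medians are bootstrap intervals over genes (10000 draws), and that of the odds ratio is a conditional one. These cover the choice of genes, which are not independent, and not the spread between libraries. A gene with a group at 0 is given as at least N-fold against a floor of 3 counts over the group.

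The main test was the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3 (TMM, filterByExpr by group, robust fit), 2-sided, with Benjamini-Hochberg adjustment over the 21883 genes that passed the filter and a threshold of 0.05. The common biological coefficient of variation was 0.169. The series title says paired, but no protocol describes a shared culture or day, so a replicate block was an alternative and not part of the main model. Nothing in the labels says whether replicates were separate cultures.

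Before the data were examined, 39 gene lists with 1240 entries were fixed, of which 1197 entries matched by symbol and 43 matched no gene. They cover osmotic stress, autophagy and lysosome, YAP and TAZ targets, neuroendocrine and non-neuroendocrine genes, stress responses, proliferation, metabolism, immune genes, matrix, signalling and cell death. They also hold lists of RNA quality and of other cell types. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 39 lists. Camera with an estimated correlation and fry were run beside it. For each list the members past the threshold were counted with p adjusted over all genes tested and adjusted over the list alone.

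The 132 named genes follow a rule fixed together with the lists. It took the 8 largest rises and the 8 largest falls among genes past the threshold with groups that did not overlap, a mean of at least 100 counts, a symbol and the same sign in limma on log2(FPKM + 1). That model held genes with an FPKM of at least 1 in at least 3 libraries, so genes below this, some with larger changes, could not be taken by this part of the rule. Genes taken whatever their values included NFAT5, AKR1B1, SLC5A3, SLC6A6, TFEB, MAP1LC3B, SQSTM1, LAMP1, YAP1, CCN1, CCN2, TXNIP, TREH and REST, and the rule also took up to 3 members of each list past the threshold with the largest change and a mean of at least 100 counts. The results of a few of the genes are not reported here.

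Other settings fixed with the lists were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, no filter on low counts, at least 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, limma with no filter, a replicate block, genes with a symbol alone, a test against a 1.2-fold change, and leaving out each of the 6 libraries. A model without the mitochondrially encoded genes and 1 on genes with a mean of at least 1 CPM were added after the data were seen. The steps were tested on simulated data with 50 genes changed at each size, drawn from genes with a mean of at least 50 counts. There edgeR recovered 46, 80, 94 and 98% of changes of 0.5, 1, 2 and 3 on the log2 scale. It made 4 false calls among 21137 genes. Recovery of genes below 50 counts, or with as many genes changed as in the data, was not tested.

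Terms of GO and KEGG with 10 to 300 genes were tested for enrichment among genes changed at least 2-fold with the hypergeometric distribution, against the 15234 (GO) or 6152 (KEGG) tested genes with any term. Because genes at a low level changed more often, 10000 draws of genes matched on mean level in 20 bins gave the expected number beside each term. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9 were used. All libraries and all columns of counts and FPKM were used, and the rows left out were genes below the filter.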

Results

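DMS114 is a human small cell lung cancer line that the labels place among the non-neuroendocrine lines of the YAP1 subtype. Poly(A)-selected, strand-specific RNA sequencing was deposited for 3 untreated control libraries and 3 libraries from cells kept in 200 mM trehalose, a non-reducing disaccharide of 2 glucose units, for 12 h. The control libraries held 58.4 M gene counts ± 2.90 (SD, n = 3; 55.7 to 61.5 M) and the trehalose libraries 57.1 M ± 3.08 (SD, n = 3; 54.4 to 60.4 M). A count of 0 in a library allowed a level of up to 0.0488 to 0.0552 CPM (counts scaled to the library total; 3 counts per library). At least 10 counts were found for 21032 genes ± 236 in control and 22185 ± 251 in trehalose libraries (SD, n = 3). Genes of the mitochondrial genome took 6.26% ± 0.213 of the counts in control and 3.68% ± 0.0486 in trehalose libraries (SD, n = 3). Levels below are CPM with TMM scaling, as mean ± SD with n = 3, and fold changes are trehalose over control from edgeR.

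The comparison asked which transcripts of DMS114 cells differed after 12 h in 200 mM trehalose. All controls were untreated, so an effect of trehalose cannot be told apart from one of the added osmolarity. Of the gene lists fixed beforehand, 20 of 24 genes of osmotic stress, 23 of 25 immediate-early genes and 17 of 19 NF-κB targets rose, while 53 of 58 genes of G1/S and DNA replication and 68 of 74 nuclear genes of the respiratory chain fell. AKR1B1, the aldose reductase that makes sorbitol from glucose, rose 8.01-fold from 125 ± 5.38 to 998 ± 19.0 CPM. CHAF1B, a subunit of the chromatin assembly factor that acts at replication forks, fell from 54.98 ± 1.27 to 11.1 ± 0.877 CPM. The autophagy receptor SQSTM1 rose 3.11-fold, while the lysosomal membrane protein gene LAMP1 stood at 342 ± 14.004 and 341 ± 0.274 CPM (adjusted p = 0.947), with a fold change whose sign differed between scalings.

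Of 21883 genes tested, 6383 were higher and 6407 lower with trehalose at an edgeR adjusted p under 0.05, and 9093 did not pass. A change of at least 2-fold was found in 4683 of them, 2727 higher and 1956 lower, and a change of at least 4-fold in 1225 higher and 361 lower. All 3 trehalose values lay on one side of all 3 control values in 14419 genes, 65.9% of those tested, where chance gives 10%. The first principal component held 66.8% of the variance, and the second, with 9.31%, set control replicate 3 at −62.6 against 36.8 and 27.1 for the other control libraries. Of the genes at least 2-fold higher, 1600 had a mean under 1 CPM in control, and of those at least 2-fold lower, 641 had a mean under 1 CPM in trehalose libraries. The p-values measure the spread between these libraries alone, which may be technical, since no label says that replicates were separate cultures. The table was deposited with no statement of strand or of how reads in overlapping genes were assigned, and 34 of the 132 named genes overlap another gene on the same strand and 44 more a gene on the other strand only, which leaves their values uncertain. All of the 132 except TFEB and LAMP1 passed the test.

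**Figure D1:**
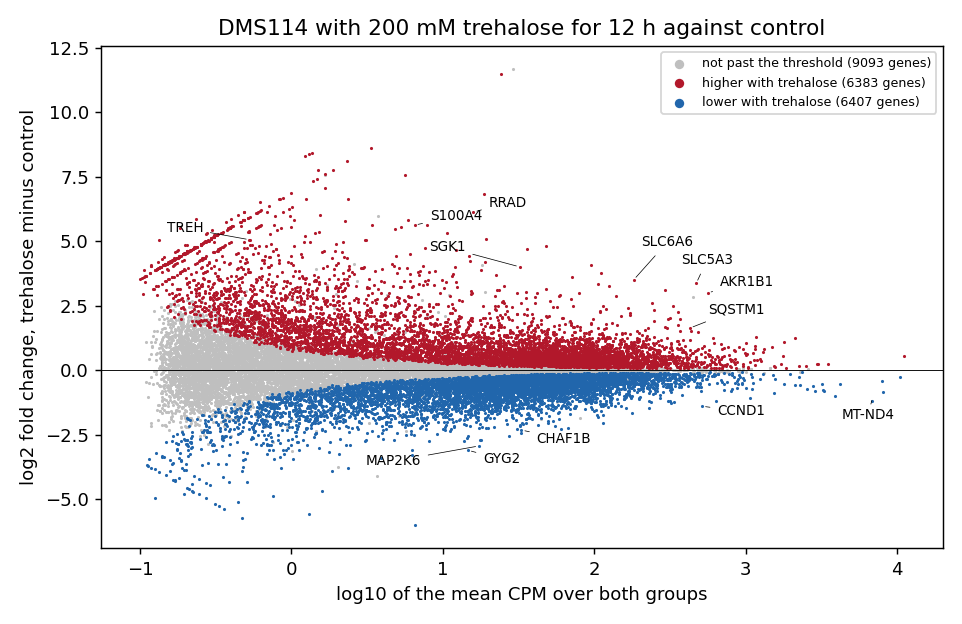
Each point is a tested gene, with the log10 of its mean CPM over both groups on the x axis and its log2 fold change, trehalose minus control, on the y axis, in red for the 6383 genes higher, blue for the 6407 lower and grey for the 9093 not past the threshold. Genes with a group at 0 are drawn at their bound, and among the genes marked by name are AKR1B1 (3.00), SLC5A3 (3.37) and SLC6A6 (3.50).

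Of the 24 tested genes of osmotic stress, 20 rose and 2 fell (20 and 3 adjusted over the list alone), with a median log2 fold change of 1.73. SLC5A3 (ENSG00000198743, hg38 chromosome 21: 34073578 to 34106260), the sodium-coupled myo-inositol transporter, rose from 83.4 ± 3.31 to 860 ± 17.7 CPM, 10.3-fold (log2 3.37, SE 0.0385, adjusted p = 2.54e-15). SLC6A6 (ENSG00000131389, chromosome 3: 14402576 to 14489349), the taurine transporter, rose from 29.5 ± 1.19 to 334 ± 20.8 CPM (log2 3.50, SE 0.0524, adjusted p = 3.01e-14). AKR1B1 (ENSG00000085662, chromosome 7: 134442356 to 134459284) had a log2 fold change of 3.00 (SE 0.0381, adjusted p = 7.27e-15). SGK1, a salt- and steroid-induced kinase (ENSG00000118515, chromosome 6: 134169248 to 134318112), rose 16.1-fold from 3.78 ± 0.585 to 60.7 ± 3.09 CPM. S100A4 rose from 0.256 ± 0.0593 to 12.7 ± 1.70 CPM (log2 5.62). NFAT5, the transcription factor that drives SLC5A3, SLC6A6 and AKR1B1 under hypertonicity, rose 1.69-fold from 87.3 ± 12.9 to 148 ± 5.62 CPM (log2 0.76, SE 0.101, adjusted p = 0.000509). The members that fell were the HSP110 family chaperone HSPA4L (−2.18) and the amino acid transporter SLC7A5 (−0.37). The list was called with a camera adjusted p = 6.69e-07, against adjusted p = 0.0764 with an estimated correlation (1.95e-09 to 0.0764 over its camera alternatives). Of the genes named here under the rule for named genes, SLC5A3, S100A4, NFAT5 and HSPA4L overlap another gene on the same strand. Members of a list that moved against the rest are mostly given by name where 5 or fewer did, and those outside the rule for named genes, such as SLC7A5, were chosen after their values were seen.

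Of the 58 genes of G1/S and DNA replication, 53 fell and 2 rose, MCM7 (0.29) and UNG (0.21), with the same counts adjusted over the list alone. The median log2 fold change was −1.02, and 31 fell at least 2-fold. CHAF1B (ENSG00000159259, chromosome 21: 36385392 to 36419015) had the largest fall of the list (log2 −2.31, SE 0.0736, adjusted p = 2.44e-11). The E2F family repressor E2F8 fell from 30.7 ± 0.637 to 8.14 ± 0.573 CPM. The list was called down with a camera adjusted p = 7.26e-15, and had adjusted p = 0.0943 with an estimated correlation (9.75e-23 to 0.0943 over its camera alternatives). Of 58 G2/M genes, 32 fell and 14 rose (33 and 15 adjusted over the list alone), with a median log2 fold change of −0.17. HMMR, a mitotic spindle protein, fell by 1.44 and the kinesin gene KIF20B by 1.34 on the log2 scale, while CKS2, a subunit of cyclin-dependent kinases, rose from 57.1 ± 1.43 to 206 ± 4.57 CPM. The G2/M list passed with a camera adjusted p = 0.0375, against adjusted p = 0.207 with an estimated correlation, and the call also ended without trehalose replicate 1 (0.0519), under upper-quartile scaling (0.0789), under stricter level filters (0.161 and 0.188) and on FPKM (0.130 and 0.137; 0.00311 to 0.207 over its camera alternatives). CCND1, the cyclin D1 gene, fell from 746 ± 10.2 to 285 ± 5.40 CPM. The cyclin-dependent kinase inhibitor CDKN1A rose from 7.32 ± 0.388 to 19.5 ± 0.650 CPM, in a list of 28 p53 targets of which 10 rose and 10 fell (camera adjusted p = 0.698).

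All 13 protein-coding genes of the mitochondrial genome fell, the same count adjusted over the list alone, with log2 fold changes of −1.18 to −0.46 and a median of −0.81. MT-ND4, a complex I subunit gene that overlaps MT-ND4L, fell from 9455 ± 462 to 4195 ± 43.3 CPM. Of the 74 nuclear genes of the respiratory chain and ATP synthase, 68 fell (69 adjusted over the list alone) and 1 rose, the complex I gene NDUFB10 (0.34), with a median of −0.57. The complex I genes NDUFA5 and NDUFB7 fell from 33.0 ± 0.853 to 11.1 ± 0.650 CPM and from 38.1 ± 2.17 to 15.3 ± 1.39 CPM. The mitochondrial list was called with a camera adjusted p = 1.39e-06 and the nuclear list with 2.81e-13. They had adjusted p = 0.2999 and adjusted p = 0.195 with an estimated correlation (3.01e-09 to 0.2999 and 5.63e-20 to 0.195 over their camera alternatives). Of 23 glycolysis genes, 10 rose and 7 fell (camera adjusted p = 0.688). PFKM and PFKL, subunits of the phosphofructokinase that commits glucose to glycolysis, fell by 2.13 and 1.11 on the log2 scale. Its subunit gene PFKP rose by 0.18 to 92.4 CPM, above PFKM (15.7) and PFKL (39.9) with trehalose. PFKFB3, which makes an activator of that enzyme, rose by 1.41. GYG2, which primes glycogen synthesis (ENSG00000056998, chromosome X: 2828822 to 2882818), fell from 26.2 ± 1.91 to 3.07 ± 0.501 CPM.

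Of the 44 autophagy genes, 24 rose and 10 fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.28. SQSTM1, which carries ubiquitinated cargo to autophagosomes, rose from 208 ± 9.79 to 646 ± 8.44 CPM (log2 1.63, SE 0.0374, adjusted p = 1.58e-12), and MAP1LC3B, an LC3 gene, from 128 ± 3.36 to 204 ± 3.996 CPM. TFE3, a transcription factor of lysosomal genes, rose by 1.58 and ATG10, an enzyme of ATG12 conjugation, fell by 1.65 on the log2 scale. TFEB, its relative, stood at 10.2 ± 0.965 and 9.64 ± 1.31 CPM (log2 −0.08, adjusted p = 0.623, but 0.02 on the log2 scale without trehalose replicate 3). The list was called up with a camera adjusted p = 0.0342, against adjusted p = 0.207 with an estimated correlation and 0.0547 without control replicate 2 (0.0199 to 0.207 over its camera alternatives). Of the 59 lysosomal genes, 26 rose and 25 fell, the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.988, 0.732 to 0.994 over its camera alternatives). Its median of −0.03, its mean of 0.07 and the upward direction of the test differed in sign. GLA, the lysosomal alpha-galactosidase, rose from 81.2 ± 4.05 to 415 ± 19.0 CPM and the fucosidase FUCA1 from 24.96 ± 0.920 to 83.1 ± 2.45 CPM, while the acid sphingomyelinase SMPD1 fell from 18.03 ± 0.601 to 4.85 ± 0.632 CPM. TREH, the enzyme that splits trehalose, had 5 counts in the controls, all in control replicate 3, and rose to 1.03 ± 0.152 CPM (adjusted p = 0.000180).

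**Figure D2:**
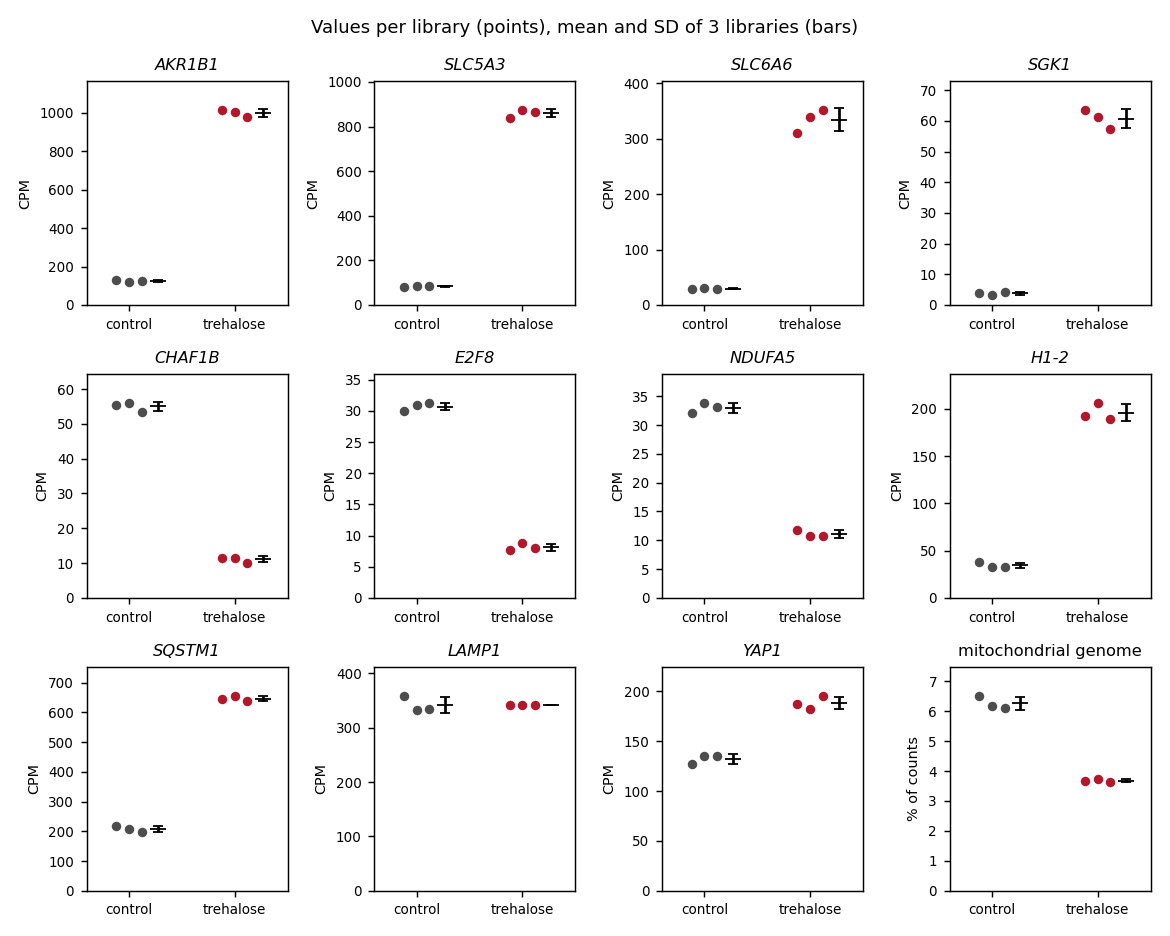
Each point is a library, with the CPM of 11 named genes and the percentage of counts from the mitochondrial genome on linear axes from 0, control in grey and trehalose in red, and the bars give the mean and SD of 3 libraries. The 3 trehalose libraries lie apart from the 3 controls for every gene drawn except LAMP1, and the mitochondrial share was 6.10% to 6.50% in control and 3.63% to 3.73% in trehalose libraries.

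Of the 25 immediate-early genes, 23 rose and 1 fell, the phosphatase DUSP2 (−0.34), with the same counts adjusted over the list alone and a median log2 fold change of 1.42. KLF4, a zinc-finger transcription factor, rose from 3.49 ± 0.539 to 27.4 ± 0.742 CPM and DUSP1, a phosphatase of MAP kinases, from 13.8 ± 1.17 to 89.0 ± 3.04 CPM. Of the 19 NF-κB and inflammation genes tested, 17 rose and 1 fell, the chemokine gene CCL5 (−0.98), again the same adjusted over the list alone, with a median of 1.39. NFKBIA, the inhibitor that NF-κB induces, rose from 68.7 ± 2.46 to 415 ± 11.5 CPM, and PTGS2, the inducible cyclooxygenase, from 0.0446 ± 0.0387 to 4.67 ± 1.03 CPM. The camera adjusted p was 2.19e-07 for the immediate-early and 1.10e-06 for the NF-κB list. They had adjusted p = 0.0764 and adjusted p = 0.171 with an estimated correlation (3.73e-10 to 0.0764 and 1.00e-06 to 0.171 over their camera alternatives). Of 17 genes of MAP kinase feedback, 12 rose and 4 fell, the same adjusted over the list alone, among the risers the transcription factor ETV4 (2.48) and among the fallers CCND1 (−1.39), SPRED2 (−0.28), SPRED1 (−0.17) and ETV5 (−0.17). This list had a camera adjusted p = 0.0339, against adjusted p = 0.195 with an estimated correlation, and lost its call on FPKM (0.0622 and 0.0728; 0.009598 to 0.195 over its camera alternatives).

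Of the 20 TGF-β targets, 16 rose and 4 did not pass (16 rose and 1 fell adjusted over the list alone), with a median of 0.88, among them the SMAD regulator SKIL (1.67) and the AP-1 gene JUNB (1.53). The camera adjusted p was 8.27e-05, and adjusted p = 0.0943 with an estimated correlation (4.71e-06 to 0.0943 over its camera alternatives). Of 15 Notch genes, 12 rose and 1 fell, the receptor gene NOTCH2 (−0.74), with the same counts adjusted over the list alone and a median of 0.61. The ligand gene DLL4 rose by 2.11 and the effector HES1 from 8.81 ± 1.10 to 37.0 ± 3.38 CPM. The Notch list had a camera adjusted p = 0.00830 and adjusted p = 0.207 with an estimated correlation (0.001598 to 0.207 over its camera alternatives). Of 44 genes of matrix and epithelial-mesenchymal transition, 22 rose and 8 fell (22 and 9 adjusted over the list alone), with a median of 0.41. The collagenase MMP1 rose from 3.47 ± 0.356 to 27.6 ± 1.71 CPM, the protease inhibitor TIMP3 from 7.99 ± 0.690 to 44.4 ± 1.151 CPM and PLOD2, which hydroxylates collagen lysines, from 11.6 ± 0.897 to 59.9 ± 3.33 CPM. The matrix list had a camera adjusted p = 0.0272, against adjusted p = 0.187 with an estimated correlation, and lost its call on FPKM (0.0556 and 0.0623; 0.0117 to 0.187 over its camera alternatives). Of 24 hypoxia genes, 12 rose, among them EGLN3 (3.44) and NDRG1 (1.86), and 3 fell, PDK1 (−1.11), P4HA2 (−0.77) and BNIP3 (−0.12), the same counts adjusted over the list alone. The hypoxia list had a median of 0.16 and a camera adjusted p = 0.0349, against adjusted p = 0.195 with an estimated correlation and 0.0533 without control replicate 3 (0.0185 to 0.195 over its camera alternatives).

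Of the 26 genes of cholesterol synthesis and uptake, 17 fell (18 adjusted over the list alone) and 3 rose, with a median of −0.51. PMVK, a kinase of the mevalonate pathway, fell from 53.1 ± 0.510 to 19.2 ± 1.09 CPM. Among the risers were NPC1L1, a cholesterol uptake transporter, from 1.51 ± 0.676 to 28.6 ± 1.16 CPM, and the sterol sensor partner INSIG1 (0.60). The camera adjusted p was 0.00299, and adjusted p = 0.195 with an estimated correlation (7.29e-05 to 0.195 over its camera alternatives). Of 19 fatty acid synthesis genes, 13 fell and 3 rose, FASN (0.66), ELOVL6 (0.62) and SCD (0.55), the same counts adjusted over the list alone, with a median of −0.39. GPAM, the first enzyme of triglyceride synthesis, fell by 1.05 and ACSS2, which makes acetyl-CoA from acetate, by 0.95 on the log2 scale. FASN and SCD encode the fatty acid synthase and the main desaturase. The list had a camera adjusted p = 0.0272, against adjusted p = 0.195 with an estimated correlation, and lost its call with at least 1 CPM in 3 libraries (0.0536) or on average (0.0570; 0.00561 to 0.195 over its camera alternatives).

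Of 25 YAP and TAZ targets, 11 rose (12 adjusted over the list alone) and 6 fell, and the list was not called (median 0.40, camera adjusted p = 0.250). YAP1 itself rose from 132 ± 4.96 to 188 ± 6.41 CPM, and its targets CCN2, MYOF and CCN1 from 2.91 ± 0.427 to 9.30 ± 0.591, from 3.07 ± 0.408 to 12.6 ± 1.59 and from 11.1 ± 0.569 to 15.5 ± 0.699 CPM. The targets that fell were DOCK5 (−1.08), AMOTL1 (−0.90), AMOTL2 (−0.67), AXL (−0.64), LATS2 (−0.62) and AJUBA (−0.59). Of 28 neuroendocrine genes, 8 rose and 10 fell (camera adjusted p = 0.772), and the median of 0.04 and mean of 0.45 were positive while the test direction was down. That mean holds STMN2 at a fitted log2 fold change of 8.34, though with 0 counts in control it is only at least 40.5-fold higher. UCHL1, BEX1 and SCG3 fell by 0.73, 0.82 and 0.79 on the log2 scale, while ISL1, CHGA and CHGB rose by 0.61, 0.44 and 0.27. REST, the repressor of neuronal genes, rose from 72.0 ± 7.94 to 111 ± 2.33 CPM. Of 27 non-neuroendocrine genes, 14 rose, among them the ephrin receptor EPHA2 from 8.82 ± 0.634 to 62.1 ± 2.85 CPM, and 9 fell, among them CAV2 by 1.38 on the log2 scale (camera adjusted p = 0.422). The counts of the neuroendocrine and non-neuroendocrine lists were the same adjusted over the list alone.

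Markers of other cell types moved beside these groups, with the same counts adjusted over the list alone. Of 9 epithelial genes, 6 rose and 1 fell, EPCAM (−3.49), and CLDN4, a tight junction gene, went from 1.10 ± 0.255 to 37.5 ± 10.96 CPM and the keratin gene KRT18 from 3.36 ± 0.427 to 19.7 ± 2.36 CPM. Of 8 leukocyte genes, 6 rose and 2 did not pass, with CD14 rising from 0.201 ± 0.0659 to 4.22 ± 0.00660 CPM. Of 7 tuft cell genes, SOX9 (0.97), AVIL (1.27), POU2F3 (5.31) and CHAT, which had 0 counts in control, rose, and 3 did not pass. The epithelial, leukocyte and tuft lists had camera adjusted p = 0.0375, 0.0382 and 0.0379, and each had adjusted p = 0.195 with an estimated correlation (0.0124 to 0.195, 0.0208 to 0.195 and 0.0264 to 0.195 over their camera alternatives). Without trehalose replicate 1 the epithelial (0.0577) and leukocyte (0.0538) calls ended. The tuft list's median of 1.05 was the same with CHAT at its bound. Of the matched entries, 9 of 15 epithelial, 8 of 13 leukocyte and 7 of 11 tuft genes passed the level filter. CHAT, KRT17 (4 counts in control), POU2F3 (12), ITGAM (14), LYZ (16), CSF1R (19) and CD79A (22) were too low in control to pass the filter there. They were tested because of their level in the trehalose libraries, which favours rises. Several risers stayed under 1 CPM with trehalose, such as LYZ (0.639), CSF1R (0.634) and CHAT (0.360). Genes under 1 CPM on average were more often at least 2-fold higher (1097 of 5968) than lower (411), and camera was not matched on level.

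Of 29 replication histone genes, whose transcripts mostly lack a poly(A) tail, 15 rose and 1 fell, H2BC9 (−0.98), the same counts adjusted over the list alone, with a median of 0.93. H1-2 rose from 34.4 ± 2.86 to 196 ± 8.76 CPM and H2BC11 from 4.30 ± 0.343 to 17.2 ± 0.271 CPM. Copies of these genes are near-identical, so reads may be assigned to the wrong copy. The camera adjusted p was 0.00442, and adjusted p = 0.168 with an estimated correlation (0.000672 to 0.168 over its camera alternatives). Of 16 nuclear and snoRNA-host long non-coding RNAs, 10 rose, among them NEAT1 (1.39) and ZFAS1 (1.31), and 5 fell, KCNQ1OT1 (−0.67), OIP5-AS1 (−0.33), SNHG8 (−0.33), NORAD (−0.27) and MALAT1 (−0.13), the same adjusted over the list alone. This list had a median of 0.57 and a camera adjusted p = 0.0375, against adjusted p = 0.195 with an estimated correlation. Its call ended without control replicate 1 (0.0516), without control replicate 2 (0.0508) and with a replicate block (0.0670; 0.0208 to 0.195 over its camera alternatives).

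Of the lists not called and not yet given, the heat shock list had 15 of 24 genes higher and 5 lower. Among the risers was HSPB8, a small heat shock protein with 0 counts in control and 4.68 ± 0.615 CPM with trehalose, at least 273-fold higher (3 counts over the group), and the fallers were HSPA4L (−2.18), HSPA8 (−0.55), HSP90AB1 (−0.54), HSPE1 (−0.35) and HSPB1 (−0.17). Its camera adjusted p of 0.0578 passed the threshold under upper-quartile scaling (0.0465), with at least 1 CPM in 3 libraries (0.0474) or on average (0.0417) and on FPKM (0.0376 and 0.0344; 0.0344 to 0.489 over its camera alternatives). Of 43 targets of ATF4, 13 rose and 24 fell (camera adjusted p = 0.0782, but 0.0185 with no filter; 0.0185 to 0.218 over its camera alternatives), with DDIT4, an mTORC1 inhibitor, rising from 19.0 ± 0.502 to 191 ± 4.24 CPM. Of 25 NRF2 targets, 12 rose and 11 fell (0.914), with the heme oxygenase HMOX1 rising from 52.98 ± 2.37 to 280.2 ± 4.03 CPM. Among 32 genes of the unfolded protein response, 11 rose and 17 fell (0.250), with DNAJB9 higher by 1.21 and CREB3L2 lower (−1.61). The ferroptosis list had 13 of 29 genes higher and 9 lower (14 and 10 adjusted over the list alone; 0.422), with SAT1, a polyamine acetyltransferase, higher by 2.45. Sugar sensing had 8 of 13 genes higher, among them TXNIP (0.59) and ARRDC4 (1.10), and MLXIPL (−1.07), HK2 (−0.77), SLC2A8 (−0.67) and MLX (−0.63) lower (0.267). Of 22 genes of the BCL2 family, the caspases and the apoptosis inhibitors BIRC2, BIRC3 and XIAP, 9 rose and 5 fell (0.357). Among the risers were MCL1 from 366 ± 6.47 to 668 ± 22.6 CPM, BMF (1.38), BOK (1.16) and BCL2L11 (0.73). The fallers included CASP9 (−0.52), BID (−0.51), BAD (−0.27) and BAK1 (−0.24).

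Of 28 interferon genes, IRF7 (2.40), MX1 (2.03), IFIT2 (1.73), DDX58 (1.58) and PARP14 (1.08) rose and 11 fell (camera adjusted p = 0.382). Antigen presentation had 9 of 18 genes higher, among them the peptide transporter TAP1 from 57.6 ± 1.62 to 182 ± 3.30 CPM, and PSMB10 (−1.23), ERAP1 (−0.71), TAP2 (−0.63) and PSMB9 (−0.36) lower (0.267). Of 22 targets of SRF and genes of actin, CCN2 (1.67), TAGLN (0.51), CCN1 (0.48), TLN1 (0.30) and TPM2 (0.11) rose and 10 fell, among them MYL9 (−1.27) and ACTA2 (−1.18; 0.204). Of 14 Wnt targets, LGR5 (2.71), AXIN2 (1.62) and NOTUM (from 2.40 ± 0.219 to 10.3 ± 1.06 CPM) rose and 6 fell (0.425), and the median of −0.25 and the downward test differed in sign from the mean of 0.04. Ribosome biogenesis had 17 of 57 genes higher and 25 lower (19 and 27 adjusted over the list alone; 0.399), with POLR1E higher by 1.18 and RRP15 lower (−1.42). Of 78 ribosomal protein genes, 19 rose and 29 fell (20 and 29 adjusted over the list alone; 0.462), with log2 fold changes of −0.71 for RPS26 to 0.61 for RPL13A. The medians of the neuroendocrine, lysosomal, ribosomal protein and p53 lists changed sign between settings. The counts adjusted over the list alone were the same in 29 of the 39 lists and differed by at most 2 genes in the other 10.

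Across the 39 lists, camera called 20, 14 of them up and 6 down, and with an estimated correlation 0 were called by camera, with 8 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0764. Fry, which tests whether a list's genes move on balance in one direction, called 36.

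**Figure D3:**
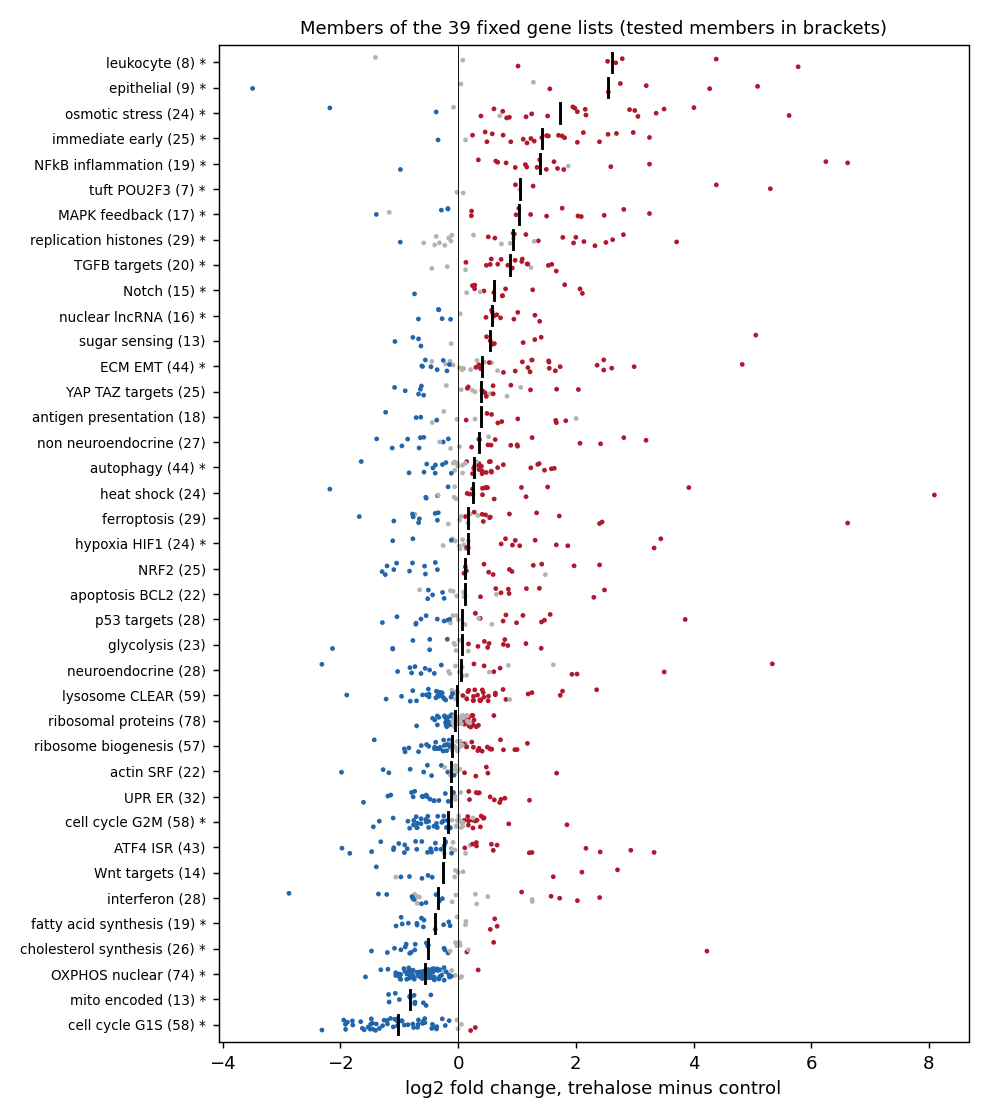
Each point is a tested member of a fixed list, with its log2 fold change, trehalose minus control, on the x axis, in red where higher, blue where lower and grey where not past the threshold, with genes that had a group at 0 at their bound, black bars at the medians and an asterisk on lists with a camera adjusted p under 0.05. The medians run from −1.02 for G1/S genes to 2.61 for leukocyte genes, and the call of each of the 20 lists with an asterisk was lost with an estimated correlation.

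The genes taken for the size of their change, among those with a mean of at least 100 counts and an FPKM of at least 1 in at least 3 libraries, were in part low in control. Genes below that FPKM, such as PTGS2 with a log2 fold change of 6.62, were not eligible. RRAD, a small GTPase (ENSG00000166592, chromosome 16: 66921679 to 66925536), rose from 0.448 ± 0.125 to 31.4 ± 1.27 CPM (log2 6.13, SE 0.156, adjusted p = 4.13e-12). RAB17, a GTPase of vesicle traffic, rose from 0.0557 ± 0.0483 to 11.1 ± 1.31 CPM. The integrin gene ITGA8 rose from 0.202 ± 0.216 to 11.5 ± 1.13 CPM (log2 5.83, but 6.94 without control replicate 3) and the orphan receptor gene GPR50 from 0.135 ± 0.117 to 6.69 ± 0.289 CPM (log2 5.64, but 5.03 without control replicate 2). The conjoined genes PEDS1-UBE2V1 and ARL2-SNX15, each of which shares exons with the genes it joins, had 48.4 ± 23.3 and 36.8 ± 10.1 CPM with trehalose against 0 counts and 0.321 ± 0.283 CPM in control, and are uncertain for that reason. PEDS1-UBE2V1 (at least 2881-fold by 3 counts over the group, adjusted p = 0.0216) did not pass without trehalose replicate 2 (0.125) or trehalose replicate 3 (0.0914; 2.34e-23 to 0.125 over its alternatives), and the log2 fold change of ARL2-SNX15 (6.82) was 7.42 without control replicate 2 and 6.24 without control replicate 1. Among the genes taken for their fall were SIGLEC10, a sialic acid receptor (log2 −3.41), the glycerol kinase GK (−3.11) and MAP2K6, a kinase of p38, from 30.7 ± 0.767 to 4.04 ± 0.334 CPM. The meiotic recombinase DMC1 (−2.88), the cilium genes CCDC113 (−2.75) and RIBC2 (−2.75) and FAM210B (−2.73), together with GYG2, completed the 8 largest falls under the same limits.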

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

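The models without the mitochondrially encoded genes and on genes with a mean of at least 1 CPM were chosen after the data were seen. Of 78 alternative values of the counts, 73 stayed within 1.5 times the main value and 5 did not. The number of genes changed at least 2-fold fell from 4683 to 1164 in limma on log2(FPKM + 1), 2260 with a pseudocount of 0.1 and 1183 with no filter (the cause was not tested). Of the 39 lists, 20 called by camera became 0 with an estimated correlation and 36 with fry, which tests another hypothesis. Leaving out 1 library at a time gave 5862 to 6231 genes higher, 6031 to 6171 lower, 4446 to 4726 changed at least 2-fold and 17 to 20 lists called. A replicate block gave 6117 higher, 6213 lower and 19 lists, and control and trehalose residuals with the same replicate number had correlations across genes of −0.0148, −0.0347 and −0.0568, against −0.0393 to 0.0748 for the other pairs, so the numbers gave no sign of pairing.

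Of 2471 values of the 132 named genes, 2453 kept their direction and side of the threshold and 11 lost the threshold, among them values of PEDS1-UBE2V1 and LDLRAD4 (0.126 on unfiltered FPKM). Another 7 reversed, none past the threshold. LAMP1, −0.003 in the main model, was 0.0110 with RLE and 0.0599 with upper-quartile scaling, 0.0328 with at least 1 CPM in 3 libraries, 0.0179 with symbols alone, 0.0393 with a mean of at least 1 CPM and −0.0294 to 0.0286 leaving out 1 library. TFEB was −0.163 to 0.0230 leaving out 1 library. The cause was not tested. Genes under a stricter filter, and lists left with fewer than 5 tested members, gave no value there. Of 691 list values, 630 kept their side, 39 lost it and 22 gained it. Besides the estimated correlation, an alternative ended the call of 9 of the 20 lists, and 11 passed in each of the others. The median log2 fold change of all genes was 0.02 with TMM and 0.08 with upper-quartile scaling, which called 6940 genes higher and 5832 lower, and 0.11 with no filter. No gene called in both the main model and one of these gene-level alternatives changed sign. Depth limited low genes, as a count of 0 allows up to 0.0552 CPM in the smallest library.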

Other observations

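The terms of GO and KEGG below, the genes named from them, the tests of deeper libraries and of S phase and the split by mean level were chosen after the results were seen. The adjusted p of each term is that of the hypergeometric test, which is not matched on level. By it, 221 of 3901 GO terms were called for genes higher and 23 for genes lower. Of 318 KEGG terms, 18 and 20 were called, so the terms below are a few picked from many. Genes of valine, leucine and isoleucine degradation were at least 2-fold lower in 19 of 45 members, against 4.87 in draws matched on level (adjusted p = 4.14e-07), and 1, AUH, was at least 2-fold higher. They included the aminotransferases BCAT1 (−1.35) and BCAT2 (−1.34), the dehydrogenase subunit BCKDHB (−1.34) and ALDH6A1 (−2.04). Of 75 peroxisome genes, 21 were at least 2-fold lower, against 8.13 in matched draws (adjusted p = 8.01e-05), such as the catalase gene CAT (−1.18) and EHHADH (−1.76), while 6 were at least 2-fold higher, such as PRDX1 (1.28). Of 137 genes of the motile cilium, 33 were at least 2-fold lower, against 15.5 in matched draws (adjusted p = 0.000576), such as IFT88 (−1.62), and 19 were at least 2-fold higher, such as the dynein gene DNAH2 (2.68).

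Among GO terms with more genes higher, G protein-coupled receptor activity had the lowest adjusted p (1.77e-10). Of its 218 members 68 were at least 2-fold higher, against 45.1 in matched draws, and 11 lower. Potassium ion transport had 32 of 104 members at least 2-fold higher, against 17.9 in matched draws (adjusted p = 9.87e-05), and 6 lower. ATP1B1, a subunit of the sodium and potassium pump, rose from 10.5 to 179 CPM (log2 4.09) and ATP1B3 by 1.12, while 17 of the 32 had a mean under 1 CPM in control. Of 76 genes of BMP signaling, 24 were at least 2-fold higher, against 10.4 in matched draws (adjusted p = 0.000640), among them the ligand gene BMP6 (2.60), and 3 were lower. The smallest p that the matched draws can give, 0.0001, was reached for these terms except potassium ion transport, with 0.0004, and G protein-coupled receptor activity, with 0.0003. The p of the matched draws was not adjusted over terms.

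The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 of 10 with the most genes higher (6383), lower (6407) and changed at least 2-fold (4683). The highest of the others was 0 in edgeR for each. Each of the others mixes control and trehalose libraries in both groups. This adds the group difference to the spread within groups, so few genes were likely to pass there. The real split also had the most lists called, 20, against 5 to 9 in the others, where no gene passed.

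Genes under 1 CPM in control that overlap no expressed gene rose at least 2-fold in 1231 of 4250, a choice by control level that favours rises, while by mean level 1097 of 5968 genes under 1 CPM were at least 2-fold higher and 411 lower, and of the 1424 over 50 kb from any expressed gene 285 were higher and 148 lower. More reads do not account for this, since the trehalose libraries were on average not deeper, at 57.1 M counts against 58.4 M in control. With all libraries thinned to 54395376 counts, the lowest trehalose library had 1054 more genes with at least 10 counts than the highest control library. That order was bound to stay, as before thinning the trehalose libraries had at least 22003 such genes and the controls at most 21296. Thinning counted genes found and did not test fold changes. Read-through from an upstream gene cannot be told apart, as 33.9% with an upstream and 26.95% with a downstream expressed neighbour rose at least 2-fold (odds ratio 1.388, 95% interval 0.975 to 1.99). Uniform background such as genomic DNA stays open too, as the median log2 fold change of the 1492 low genes over 50 kb from any expressed gene was 0.461 with an interval of 0.354 to 0.558, neither at least 1 nor clearly under 0.5, the values chosen in advance for and against it. A biological rise with the trehalose treatment stays open beside these.

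All 13 mitochondrial and 68 of 74 nuclear genes of the respiratory chain fell, with list calls that were lost with an estimated correlation (adjusted p = 0.2999 and 0.195). The choice among 4 scalings does not account for it, since the higher of the medians of both lists was −0.5033. These scalings lay close together, with medians of all genes of 0.01 to 0.08 on the log2 scale, so they could move the lists little. Other kinds of scaling were not tested. A trend with the length and GC content of the longest GENCODE transcript per gene was removed for the nuclear but not the mitochondrial list. The nuclear list's median was then −0.5279 (95% interval −0.670 to −0.462), against 0.0187 for ribosomal proteins, so this trend does not account for its fall. The longest transcript may not be the one expressed, which leaves a bias with the length of the expressed transcript open. A hypothesis on these data, for which no test was run, is that the treatment itself lowered these transcripts. Untreated controls cannot separate trehalose from its osmolarity. Differences between cultures or in RNA handling that go with the groups were not tested and stay open.

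Of 29 replication histone genes 15 rose and 1 fell (median 0.93, 95% interval 0.261 to 1.36), with a list call (adjusted p = 0.00442) that was lost with an estimated correlation (adjusted p = 0.168). A rise of the genes of G1/S and DNA replication was taken as the mark of more cells in S phase. Their median was −1.02 (95% interval −1.20 to −0.762). This fall was known when the test was chosen, and the phase of the cells was not measured, so a change in S phase stays open. Carry-over of RNA without a poly(A) tail cannot be told apart, because 9 other such RNAs were tested and their median of 0.436 had an interval of −0.996 to 0.908. Of these, RN7SL1 and RN7SL2 fell and SNORD17 rose, and a biological rise of polyadenylated histone transcripts was not tested.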
